A study of Mus musculus with 20 samples.

How the data were processed

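Suz12 ChIP-seq was analysed in wild-type E14 mouse embryonic stem cells before and after inhibition of transcription by DRB (100 µM) or triptolide (10 µM). Of the 20 samples of the series, 8 Suz12 libraries had a list that was used, with 2 each at DRB 0 h, DRB 12 h, triptolide 0 h and triptolide 9 h. The other 12 samples were not analysed here. Per the submitters' processing notes, the authors aligned reads with Bowtie and called peaks with MACS on mm10 (GRCm38); no versions are given. Each deposited list holds the peaks of 1 library without a score, and per the file headers it also holds raw read counts over those peaks in 13 columns. The deposited counts are whole numbers without normalization. The column names placed 8 of the 13 columns in the groups of the lists, and the other 5 were not used. The triptolide columns carry replicate numbers. The DRB columns give the group, an index and a lane. Those of index TGACCA also carry a digit that is not a replicate number of the labels. DRB counts are therefore named by index and not by replicate.

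Peaks of all 8 lists that overlapped by 1 bp were merged into 11943 regions. A region was kept if it had a peak in all 8 lists, gained if in all 4 treated lists and in no untreated list, and lost in the reverse case. Genes were the 21631 protein-coding genes of the GRCm38.p6 annotation on the autosomes and X. This annotation has no strand, so a gene counted as bound when a peak lay within 1 kb of either annotated end, in place of the start site that had been planned. No genome sequence was used, so results on CpG islands were not computed and the background of each enrichment was every gene with no peak in any untreated list. The 20 gene lists were fixed before the data were examined. Names in them were matched to gene symbols, and to a synonym only where the name was no gene's own symbol. The genes named in the text were set by rule, leaving out symbols of the form Gm with a number or ending in Rik. The rule takes 12 gained and 6 kept genes, up to 5 lost genes, and 5 genes each with peaks under DRB alone or triptolide alone, by highest mean percentile. Of each gene list it takes up to 4 gained members or, with none gained, 2 members in alphabetical order. Some genes that this rule takes are not reported here. The lists hold no scores, so the percentile was the rank within a list of the mean count in the 2 libraries of that list's group, and the stricter peak threshold was the median width of 1357 bp.

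Ratios of list measures, from geometric means, were tested by two-sided exact permutation of 4 against 4 lists (70 arrangements). Gene lists were tested by two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 20 lists. A test of the counts was added after the files were seen to hold them, and its settings were chosen after an early look had shown the direction of the counts. The counts of a region were those over its widest peak. They were tested in edgeR by quasi-likelihood with TMM scaling, 4 groups and no filter, for each drug, for the mean of both drugs and for the difference between them, at an adjusted p under 0.05. Changes are relative, since no library totals were used, and CPM stands for counts per 1e6 reads counted over the regions, after scaling. Of 7963 genes with a peak in any list, a few, Pax3 among them, had no counted region at an end. Intervals over regions came from 1000 bootstrap draws of regions and hold no spread between libraries.

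The libraries had 1323926 to 7340023 reads counted over the regions. Replicates differed beyond counting noise, with a chi-square per degree of freedom of 3.03 at DRB 0 h, 8.65 at DRB 12 h, 3.23 at triptolide 0 h and 2.47 at triptolide 9 h. The test was checked on simulated data with 200 changed among 11943 regions. Over both drugs it recovered 40.7% of 1.5-fold, 86.5% of 2-fold and 98.5% of 3-fold changes, and called 19 of 11743 unchanged regions. Signs of the simulated changes were drawn at random, so the check does not cover a shift of many regions in 1 direction. For DRB alone it recovered 47.3% and for triptolide alone 48.6% of 2-fold changes. In simulated lists all 200 gained and all 200 lost regions were recovered, with 201 called lost. Each had been placed in every list of its side and in none of the other, the pattern that the rule asks for. This checks the code alone and does not cover peaks missed in a list.

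Alternatives for the lists, set before the data were examined, were wider peaks alone, lists of equal length (the 5116 peaks of highest percentile), an overlap of 0.5 of the shorter interval, windows of 2.5 and 0.5 kb, a rule of 3 of 4 lists, peaks closer than 1 kb merged, absence from all 4 untreated lists, other permutation schemes, and leaving out each list for peaks, covered length, genes with a peak and regions of all 8 lists. Leaving out each list for regions of 1 drug, for the overlap and for the gene lists, every alternative for the number of gained genes, and permutation of genes within each drug were chosen after seeing the data. So were the alternatives for the counts: DESeq2 size factors, the sum of all counts, the sum over kept regions, DESeq2's own test, a mean count of at least 100, regions in at least 2 lists, the narrowest peak, a replicate block, and leaving out each library. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.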

Results

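Suz12 is a core subunit of Polycomb repressive complex 2 (PRC2), the complex that methylates lysine 27 of histone H3. Its binding was measured by ChIP-seq in wild-type E14 mouse embryonic stem cells grown in serum with LIF on gelatin. Transcription was blocked with DRB, an inhibitor of the kinase that releases RNA polymerase II into elongation, or with triptolide, which acts on the TFIIH helicase at initiation. DRB was given at 100 µM and triptolide at 10 µM. The question is where Suz12 binds once transcription has stopped. Peak lists and read counts of 8 Suz12 libraries were analysed, with 2 libraries in each of 4 groups: DRB at 0 h, DRB at 12 h, triptolide at 0 h and triptolide at 9 h. The series design calls the replicates biological. Nothing says whether they came from separate cultures, so p-values of permutation and edgeR tests measure the spread between these libraries alone. Fisher's exact tests take genes or regions as units, which are not independent of each other, and their p-values hold no spread between libraries. The other 12 samples of the series (shorter treatments, H3K27me3 and RNA polymerase II) were not analysed here. The reads counted over Suz12 regions came to 1323926 and 4396744 in the DRB 0 h libraries and to 2416530 and 7340023 at 12 h. They came to 3699979 and 3070233 in the triptolide 0 h libraries and to 4334366 and 4441617 at 9 h. The names of the count columns give lane numbers 1 and 4 for untreated libraries and 3 and 6 for treated ones. Some libraries share both index and lane number and so came from separate runs, but no lane number holds both untreated and treated libraries, and lane cannot be told apart from treatment.

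Suz12 peaks appeared at the ends of many genes after either inhibitor, and 872 protein-coding genes had a peak in all 4 treated lists and in no untreated list. The named genes follow a rule set before the data were examined. Gene ends in place of start sites, and read counts in place of peak scores, entered that rule later. Sox2, Utf1, Lefty2, Fgf4, Zfp36, Fos, Egr2, Atf3, Srf, Tbx3, Dnmt3l, Foxd3, Olfr94 and Olfr95 lie outside it and were chosen after their values were seen. Among the genes that gained a peak were Klf2, Klf4, Sox2 and Mycn, transcription factors of the pluripotent state, and Sall1, a zinc finger regulator of kidney and limb development. Only 1 gene, Zfp365, had a peak in all 4 untreated lists and in no treated list. A further 3003 genes, 38 of the 39 Hox genes among them, had a peak in all 8 lists. A gene was counted where a peak lay within 1 kb of either annotated end, since the annotation used carries no strand.

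The lists held 6340.5 ± 771 peaks at DRB 0 h and 10710.5 ± 309 at DRB 12 h (SD, n = 2 each). They held 5922 ± 1140 peaks at triptolide 0 h and 8579 ± 2017 at triptolide 9 h (SD, n = 2 each). Treated lists were 1.56 times as long as untreated ones, by 1.70 for DRB and 1.44 for triptolide (two-sided exact permutation p = 0.0286, n = 4 against 4). This is the smallest p that the 70 arrangements allow, and within a drug 2 lists against 2 cannot go below p = 0.333 in an exact test. Genes with a peak at an end numbered 3787.5 ± 449 in untreated and 6367 ± 1008 in treated lists (SD, n = 4 each), a ratio of 1.67 (exact permutation p = 0.0286). Covered length went from 11.1 ± 1.68 Mb to 15.9 ± 1.58 Mb (SD, n = 4 each), a ratio of 1.44 (exact permutation p = 0.0286). Median peak width did not differ beyond the spread of the lists, at a ratio of 0.936 (exact permutation p = 0.6, n = 4 against 4). The percentage of peaks within 1 kb of a gene end was 63.2% ± 1.88 in untreated and 64.9% ± 1.87 in treated lists (SD, n = 4 each, exact permutation p = 0.286). Permuting within each drug gave p = 0.0556 for peaks, genes and covered length, the smallest that its 36 arrangements allow in an exact test. Without any 1 of the untreated lists (DRB 0 h replicate 1 or 2, triptolide 0 h replicate 1 or 2), the exact permutation p for peaks and for genes was 0.0571. With covered length kept to peaks of at least the median width of 1357 bp, the ratio was 1.35 (exact permutation p = 0.0857).

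**Figure D1:**
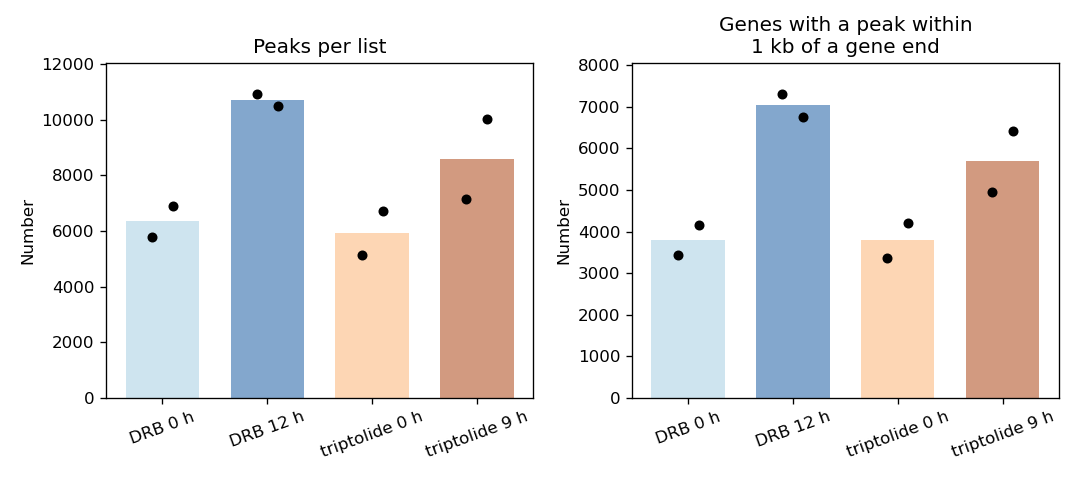
Left, Suz12 peaks per list, and right, protein-coding genes with a peak within 1 kb of either gene end, by group. Bars start at 0 and show the mean of 2 lists, and points show each list; the 4 treated lists hold 7153 to 10929 peaks and the 4 untreated lists 5116 to 6886.

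Over the union of all lists there were 11943 separate regions. Of these, 4281 had a peak in all 8 lists (kept regions, median width 2314 bp) and 1065 in the 4 treated lists alone (gained regions, median width 1451 bp). The share of regions within 1 kb of a gene end was 71.0% for kept and 70.7% for gained regions. The single region lost in all treated lists lay at Zfp365 (chromosome 10, 67911489 to 67912855, GRCm38). List length enters these counts: with every list held to its 5116 highest-ranked peaks, 503 regions were gained and 355 lost. Without triptolide 9 h replicate 1, the shortest treated list, 2131 regions and 1690 genes were gained. The number of lost regions came to 11 without DRB 0 h replicate 1, to 7 without DRB 12 h replicate 2, to 5 without triptolide 0 h replicate 1, and to 4 without DRB 12 h replicate 1 or without triptolide 9 h replicate 2.

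The gained genes whose treated lists ranked them highest by read count were Tlnrd1, Isyna1, Ssbp4, Irf2bpl, Gas2l1, Fdps, Cdk6, Sall1, Anp32a, Psmd8, Slc38a1 and Slc12a5. In edgeR's quasi-likelihood test across both drugs, Suz12 counts at all 12 rose. They were chosen for peaks in the treated lists alone of the same libraries, so higher treated counts come in part with the choice. Sall1 (chromosome 8, 89040769 to 89046800) went from 46.2 ± 3.17 to 281 ± 5.77 counts per 1e6 reads (CPM) under DRB and from 49.2 ± 3.91 to 277 ± 48.0 under triptolide (SD, n = 2 each). Its log2 fold change over both drugs was 2.56 ± 0.11 (SE, adjusted p = 9.92e-08). Irf2bpl (chromosome 12, 86881550 to 86884995) rose by 2.43 ± 0.12 (SE, adjusted p = 1.27e-07). Slc38a1, an amino acid transporter (chromosome 15, 96640545 to 96643427), rose by 2.35 ± 0.12 (SE, adjusted p = 1.54e-07). Tlnrd1 (chromosome 7, 83881859 to 83884862) rose by 2.27 ± 0.12 (SE, adjusted p = 1.54e-07). Anp32a rose by 1.80 ± 0.12, Gas2l1 by 1.53 ± 0.11, and the region shared by Isyna1 and Ssbp4 by 1.52 ± 0.10 (SE). The cyclin-dependent kinase gene Cdk6 rose by 1.06 ± 0.09, Psmd8 by 1.07 ± 0.10, and Slc12a5, a neuronal potassium-chloride transporter, by 0.77 ± 0.11 (SE). The smallest change among the 12 was at Fdps, which encodes an enzyme of the cholesterol pathway, at 0.56 ± 0.09 (SE, adjusted p = 2.28e-04). The region counted for Fdps (chromosome 3, 89087606 to 89093670) overlaps its gene only at the lower-coordinate end, from 89093588. That for Psmd8 (chromosome 7, 29170315 to 29173344) lies outside the annotated gene. That for Slc12a5 (chromosome 2, 164996546 to 164999162) lies near the upper-coordinate end of its gene.

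Pluripotency genes were gained more often than other genes. Of 30 members with no peak in any untreated list, 8 gained one: Fgf4, Klf2, Klf4, Lefty2, Myc, Mycn, Sox2 and Utf1. This is 26.7% against 5.04% of other eligible genes (odds ratio 6.85, Fisher's exact p = 9.23e-05, adjusted p = 6.15e-04 over 20 lists). For all gene lists the background was every gene with no untreated peak, olfactory receptors included, not the planned genes with CpG island promoters. Whether CpG islands account for such differences was not tested. The odds ratio was 3.94 without triptolide 9 h replicate 1 (adjusted Fisher's exact p = 0.0119) and 11.7 at equal list length. Klf2 (chromosome 8, 72318700 to 72321209) went from 23.2 ± 2.53 to 131 ± 1.39 CPM under DRB and from 24.2 ± 1.44 to 112 ± 6.47 under triptolide (SD, n = 2 each). Its log2 fold change was 2.34 ± 0.12 over both drugs (SE, edgeR adjusted p = 1.54e-07). Mycn (chromosome 12, 12938887 to 12942037) rose by 2.08 ± 0.14, Klf4 (chromosome 4, 55529920 to 55533285) by 1.72 ± 0.11 and Myc (chromosome 15, 61984763 to 61988423) by 1.49 ± 0.11 (SE). Of the 32 members of the list, 18 had a peak in any peak list. Pou5f1 and Nanog, named after their values were seen, had none. Over all 18 pluripotency regions with counts, 14 rose and none fell over both drugs, at a median of 1.07 (17 rose with kept-region scaling). Adjusted over the list alone, 15 rose. Of these 18 members 16 entered through peaks in treated lists alone, so higher treated counts come in part with that selection. Of the 4 that did not pass, Tbx3, kept in all 8 lists, had 0.14 ± 0.12 and Dnmt3l 0.28 ± 0.28 (SE).

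Immediate early genes, which signalling switches on within minutes, were also gained more often. Of 10 members free of Suz12 peaks in untreated cells, 5 gained one: Dusp1, Dusp6, Ier3, Myc and Zfp36 (odds ratio 18.8, Fisher's exact p = 6.80e-05, adjusted p = 6.15e-04). Myc is a member of both lists. Dusp6 (chromosome 10, 99263382 to 99264984), which encodes a phosphatase of ERK, rose by 1.60 ± 0.17, Ier3 (chromosome 17, 35821372 to 35822693) by 1.08 ± 0.14 and Dusp1 (chromosome 17, 26507371 to 26508528) by 0.76 ± 0.16 (SE). Over both drugs 12 of the 23 regions of the list rose and 7 fell, with the same counts adjusted over the list alone, and 10 of the 23 members entered through peaks in treated lists alone, which favours a rise. Fos, Egr2 and Atf3, with peaks in all 8 lists, fell by 0.54, 0.47 and 0.51 (−0.19, −0.13 and −0.16 with kept-region scaling), while Srf, also in all 8, rose by 0.34 ± 0.13 (SE). Scaled to the kept regions, 14 rose and 2 fell.

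Olfactory receptor genes gained no peak: 0 of 1103 eligible genes against 5.43% of other genes (odds ratio 0, adjusted Fisher's exact p = 5.05e-25). Of the 3 members with a peak in any list, Olfr94 and Olfr95 had one in all 8, and 2 of the 3 regions had lower counts over both drugs, also when adjusted over the list alone and in neither case with counts scaled to the kept regions. Olfr1 and Olfr10 had no peak in any list. None of the other 17 of 20 lists passed for gained genes, and Hox clusters and developmental regulators, with 0 and 1 eligible members, could not. The closest was that of PRC2 and PRC1 subunits, with Epop, Ring1 and Aebp2 gained of 22 eligible (odds ratio 2.96, adjusted Fisher's exact p = 0.491). Epop, which encodes a PRC2 accessory protein (chromosome 11, 97627563 to 97630241), rose by 2.03 ± 0.19, Ring1 (chromosome 17, 34024210 to 34025832) by 1.21 ± 0.20 and Aebp2 (chromosome 6, 140622497 to 140624562) by 0.81 ± 0.17 (SE). In that list 9 of 20 regions rose and 4 fell, with the same counts adjusted over the list alone (13 rose and 2 fell with counts scaled to the kept regions).

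Hox genes kept their Suz12 peaks, and their share of the counts was lower after both inhibitors. Of 39 Hox genes, 38 had a peak in all 8 lists. Over both drugs the counts of their 28 regions fell by a median of 0.55 on the log2 scale, with 28 of 28 regions lower in the edgeR test and 28 adjusted over the list alone. Hoxa10 (chromosome 6, 52228292 to 52238651) went from 1092 ± 104 to 718 ± 53.6 CPM under DRB and from 1149 ± 52.3 to 716 ± 37.7 under triptolide (SD, n = 2 each), a log2 change of −0.64 ± 0.08 (SE, adjusted p = 3.45e-05; −0.30 with kept-region scaling). With counts scaled to the kept regions the Hox median was −0.21, with 17 regions lower and 0 higher. Every scaling gave the same sign for the Hox median. In TMM-scaled CPM every treated library lay below every untreated one at 26 of the 28 Hox regions (chance gives 1.43% of regions per direction). The same held at 1452 of 2803 regions of kept genes, so the fall was not limited to Hox genes. This separation of libraries was not counted under the other scalings. Kept regions in the highest quartile of count density had a median of −0.46 (−0.12 with kept-region scaling). Those in the lowest had −0.32 (0.02 with kept-region scaling). Hox regions were not tested against kept regions of like density.

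Regulators of lineage choice behaved like Hox genes. Of 40 developmental regulators, 39 had a peak in all 8 lists. Of the 38 with counts, 35 fell and 1, Foxd3, rose over both drugs, with the same counts adjusted over the list alone, at a median of −0.57 (−0.22 with counts scaled to the kept regions, 25 lower and 2 higher). In TMM-scaled CPM all treated libraries lay below all untreated ones at 33 of the 38 and above them at 1. Over all kept genes the numbers were 1452 and 256 of 2803 regions. Cdx2, the trophectoderm regulator (chromosome 5, 147300905 to 147308480), changed by −0.57 ± 0.08 (SE, adjusted p = 6.11e-05; −0.22 with kept-region scaling). The kept genes with the highest rank by read count in untreated lists were Tbx1, Tbx2, Six3, Lmx1b, Skor1 and Lhx5, a choice from the same libraries that favours lower treated counts. All 6 had lower counts over both drugs, from −0.41 ± 0.09 at Skor1 (adjusted p = 0.00246) to −0.71 ± 0.06 at Lmx1b (SE, adjusted p = 5.72e-06; −0.36 with kept-region scaling). Tbx1 (chromosome 16, 18579806 to 18592425), a regulator of pharyngeal development, changed by −0.59 ± 0.09 (−0.25 with kept-region scaling) and Six3 (chromosome 17, 85607279 to 85624578), a forebrain regulator, by −0.53 ± 0.07 (SE; −0.18 with kept-region scaling). Skor1, scaled to the kept regions, was no longer called (−0.06, adjusted p = 0.414). At Zfp365, the lost gene, counts went from 53.6 ± 6.06 to 13.9 ± 1.61 CPM under DRB and from 56.8 ± 1.30 to 15.3 ± 1.90 under triptolide (SD, n = 2 each), a log2 change of −1.91 ± 0.14 (SE, adjusted p = 1.64e-06).

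**Figure D2:**
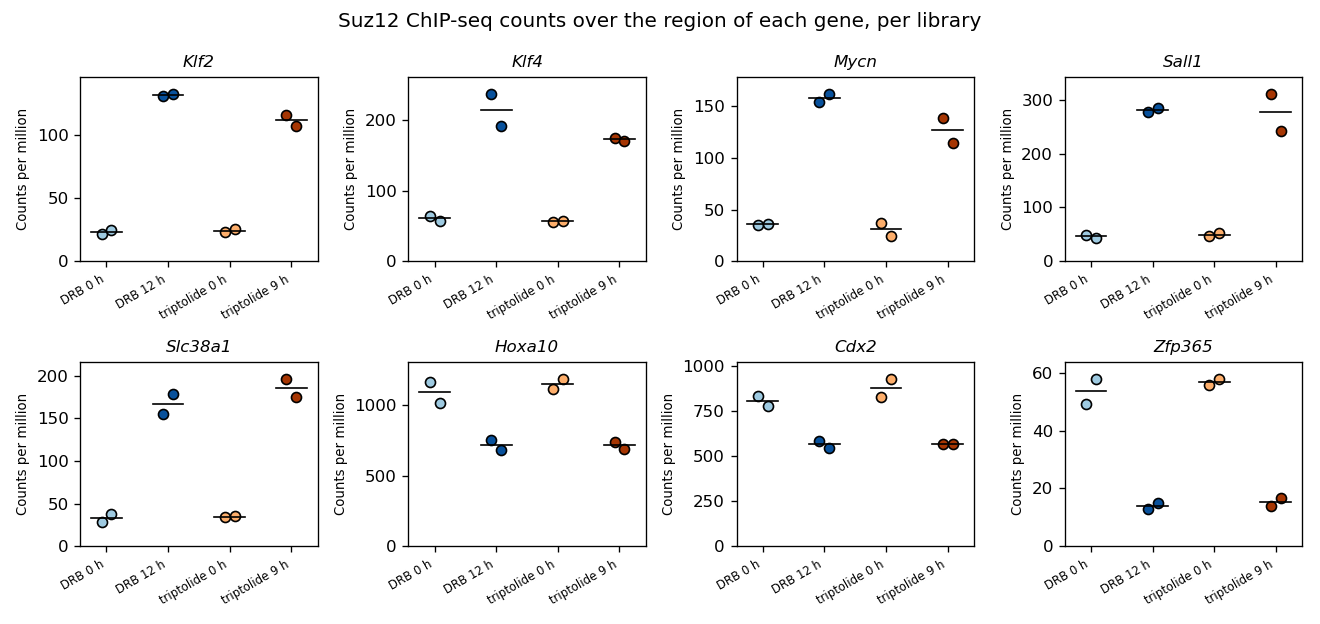
Suz12 ChIP-seq CPM (linear axes from 0) over the regions of 8 genes, by group. Each point is 1 library and each line the mean of 2; treated libraries lie above untreated ones at Klf2, Klf4, Mycn, Sall1 and Slc38a1 and below them at Hoxa10, Cdx2 and Zfp365.

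Across all regions, counts rose at 3339 and fell at 3451 of 11943 over both drugs (edgeR, adjusted p under 0.05, TMM scaling). Of the gained regions 930 rose and 0 fell, at a median log2 change of 0.88 (956 passed at an unadjusted p under 0.05). Of the kept regions 440 rose and 2528 fell, at a median of −0.38; with counts scaled to the kept regions 1102 rose and 1069 fell. In TMM-scaled CPM all treated libraries lay above all untreated ones at 636 of 732 regions of gained genes. At regions of kept genes they lay below them at 1452 and above them at 256 of 2803. Gained regions took 2.32 to 2.59% of the counts in untreated libraries and 5.46 to 5.86% in treated ones. The split into higher and lower rests on the scaling, since library totals are not given in the sources used here. With counts scaled to the kept regions, 5658 regions rose and 1343 fell, so that the share of higher calls went from 49.2 to 80.8%, and with the sum of all counts 4654 rose and 2238 fell. The median of all regions was 0.05 with TMM, 0.25 with the sum and 0.39 with kept regions. Gained regions stood 1.26 above kept regions in median log2 change with TMM, at 1.22 and −0.04 with kept-region scaling. The gained regions were chosen from lists of the same libraries, so part of this difference comes with the selection. Read in the libraries of the other drug, regions gained in DRB lists stood 1.01 above kept regions in triptolide counts. Regions gained in triptolide lists stood 1.14 above them in DRB counts (bootstrap 95% intervals over regions, 0.977 to 1.03 and 1.11 to 1.18). These intervals hold no spread between libraries, and kept regions were chosen from all lists, those of the other drug included.

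DRB alone gave the longest lists. Immediate early genes stood out, with 9 of 10 eligible members, Myc and Dusp6 among them, carrying a peak in both 12 h lists and in no untreated list (odds ratio 66.0, Fisher's exact p = 4.71e-08, adjusted p = 4.71e-07). Pluripotency genes (10 of 30, odds ratio 3.66, adjusted Fisher's exact p = 0.00968) and PRC2 and PRC1 subunits (7 of 22, odds ratio 3.41, adjusted Fisher's exact p = 0.0483) were also gained more often. Ribosomal protein genes (1 of 83, odds ratio 0.0886, adjusted Fisher's exact p = 0.00354) and olfactory receptor genes (0 of 1103, odds ratio 0, adjusted Fisher's exact p = 6.24e-63) were gained less often than other genes. Against its own 0 h lists, DRB at 12 h gained 2874 regions and lost 12. With equal list length the values were 761 and 506, and lost regions came to 136 without DRB 0 h replicate 1, 56 without DRB 12 h replicate 2, 25 without DRB 0 h replicate 2 and 24 without DRB 12 h replicate 1. In counts, 2156 regions rose and 2297 fell (edgeR adjusted p under 0.05), and without the 0 h library of index TGACCA 1089 rose and 1203 fell. Scaling to the kept regions gave 3646 that rose and 601 that fell.

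Triptolide gained fewer regions from shorter lists. Klf2, Mycn and Fgf4 had log2 changes of 2.20 ± 0.16, 2.02 ± 0.19 and 2.07 ± 0.17 at 9 h (SE, edgeR adjusted p of 1.09e-05, 5.14e-05 and 2.90e-05). Pluripotency genes (9 of 30, odds ratio 7.60, adjusted Fisher's exact p = 1.87e-04) and immediate early genes (5 of 10, odds ratio 17.7, adjusted Fisher's exact p = 5.98e-04) were gained more often than other genes, and olfactory receptor genes less often (0 of 1103, odds ratio 0, adjusted Fisher's exact p = 1.79e-26). Against its own 0 h lists, triptolide at 9 h gained 1337 regions and lost 70. With equal list length the values were 719 and 664. Gained regions came to 3283 without triptolide 9 h replicate 1 and to 2213 without triptolide 0 h replicate 2, and lost regions to 303 without triptolide 0 h replicate 1 and 290 without triptolide 9 h replicate 2. In counts 2307 regions rose and 2611 fell (edgeR adjusted p under 0.05). Without 0 h replicate 1 or 2, or 9 h replicate 1 or 2, the numbers that rose were 1319, 1418, 1299 and 1311, and those that fell 1663, 1703, 1187 and 1118. Scaling to the kept regions gave 4315 that rose and 595 that fell.

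Most genes gained under triptolide were also gained under DRB, though doses and times differ. Of 17170 genes with no untreated peak, 2069 were gained under DRB and 924 under triptolide, and 872 under both, against 111 for independent sets (odds ratio 211). The odds ratio was 823 without DRB 12 h replicate 1, 112 without DRB 12 h replicate 2 and 465 at equal list length. Over regions called in treated lists alone, 1065 were shared against 600 for independent sets (odds ratio 16.1, Fisher's exact p = 2.04e-239, with regions not independent of each other). Across 11943 regions the log2 changes of the drugs had a Pearson correlation of 0.883 and a Spearman correlation of 0.892, and 88.3% had the same sign. Each drug had its own 0 h libraries, and regions are not independent replicates. Counts rose under both drugs at 1703 regions against 416 for independent sets, and fell under both at 1975 against 502. The list fold was 1.18 times as large for DRB as for triptolide (exact permutation p = 0.611, smallest possible 0.0556).

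Some genes had a peak under 1 drug alone. Under DRB alone the highest by read count were Shank3, Socs3, Junb, Lrcol1 and Etv6. Socs3, a feedback inhibitor of LIF signalling (chromosome 11, 117967162 to 117969760), rose by 2.13 ± 0.20 under DRB and by 0.89 ± 0.19 under triptolide (SE, adjusted p of 5.35e-05 and 0.00348). Junb (chromosome 8, 84976995 to 84979154) rose by 1.86 ± 0.20 and 0.53 ± 0.20 (SE, adjusted p of 9.81e-05 and 0.0490). Etv6 and Lrcol1 also rose under both drugs, and Shank3 passed for neither alone (0.37 ± 0.17 and 0.42 ± 0.16, SE). Of the 497 regions with peaks under DRB alone, 128 rose and 0 fell in DRB counts and 80 rose and 4 fell in triptolide counts (245 and 0, and 218 and 0, with kept-region scaling). Of the 12 regions with peaks under triptolide alone, 6 rose and 0 fell in triptolide counts and 0 rose and 1 fell in DRB counts (8 and 0, and 3 and 0, with kept-region scaling). None of either set differed between the drugs in edgeR's test of the difference, and 8 and 4 did at an unadjusted p under 0.05. Among the genes with a peak under triptolide alone were Tuba4a, Ctu1, Lhb and Wrap53. Tuba4a and Ctu1 rose under DRB too, by 1.02 ± 0.17 and 0.92 ± 0.16 (SE). The region at Wrap53 (chromosome 11, 69559404 to 69561368) had 1.24 ± 0.19 under triptolide and −0.03 ± 0.21 under DRB (SE). That region lies outside the annotated gene, beyond its lower-coordinate end at 69561754. The regions counted for Lrcol1 (chromosome 5, 110341705 to 110343509) and Lhb (chromosome 7, 45414835 to 45416679) also lie outside their genes. That for Shank3 (chromosome 15, 89556191 to 89559486) lies near the upper-coordinate end of its gene. The difference between the drugs passed at 2 of 11943 regions by edgeR and 3 by DESeq2 (193 and 91 at an unadjusted p under 0.05). With a replicate block it passed at 5 regions with a higher and 38 with a lower change under DRB than under triptolide. The block pairs triptolide libraries by replicate number and DRB libraries by index, where the names of index TGACCA also share an added digit. No label says that paired libraries share a culture. With counts scaled to the kept regions and no block, the difference passed at 0 regions (206 at an unadjusted p under 0.05). It passed at 0 regions without either DRB 0 h library or without any 1 of the triptolide libraries, and at 7 without the DRB 12 h library of index TGACCA.

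**Figure D3:**
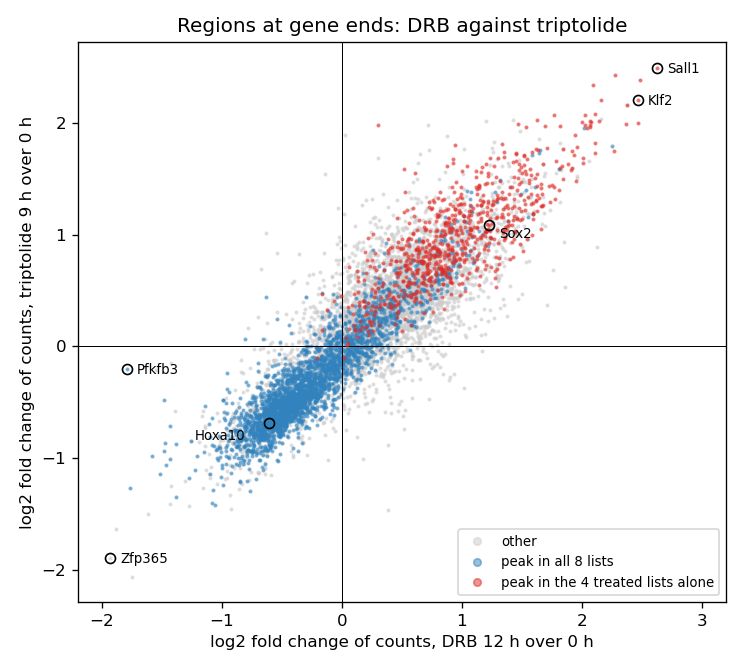
Log2 fold change of Suz12 counts (TMM scaling) under triptolide at 9 h against DRB at 12 h, each over its own 0 h libraries. Each point is 1 region at a gene end; red points had a peak in the 4 treated lists alone, blue points in all 8 lists and grey points neither, and labelled rings mark 6 genes, with Pfkfb3 away from the diagonal.

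The remaining lists were those of genes active in most cells and of other cell types. Most regions of the active gene groups entered through peaks in treated lists alone. This held for 8 of 9 ribosomal, 5 of 5 NADH dehydrogenase and 11 of 11 splicing members. A rise without a fall can come with that selection, to an extent that was not measured. For ribosomal protein genes 5 of 9 regions rose, with Rpl19 gained at 0.91 ± 0.14 (chromosome 11, 98021863 to 98023250). For NADH dehydrogenase subunits 3 of 5 rose, with Ndufa13 gained at 2.09 ± 0.12 (chromosome 8, 69901734 to 69903595), and for glycolysis 3 of 4 rose, with Pkm gained at 0.75 ± 0.14 (SE). For splicing factors 5 of 11 rose, with Srsf9 gained at 1.46 ± 0.12 and Sf3b2 at 0.78 ± 0.19 (SE). For transcription and elongation machinery 4 of 8 rose, with Hexim1, an inhibitor of the elongation kinase, gained at 1.82 ± 0.16 and Polr2b at 0.84 ± 0.12 (SE). The region counted for Pkm (chromosome 9, 59679954 to 59681209) lies outside the annotated gene. So do those for Sf3b2 (chromosome 19, 5272111 to 5273584) and Polr2b (chromosome 5, 77308734 to 77310240). For heat shock and chaperone genes 2 of 8 rose, with Hsph1 gained at 1.34 ± 0.18 (SE), and for DNA replication and cell cycle genes 6 of 9, while Aurka and Aurkb had no peak in any list. None of the regions of these 7 lists fell, and the counts adjusted over the list alone were the same. Kept-region scaling gave 5, 4, 4, 8, 6, 4 and 9 regions that rose, in the order given, and again none that fell. For proteasome subunits 3 of 11 rose, Psmd8 among them, and 2 fell, with the same counts adjusted over the list alone (6 rose and 1 fell with counts scaled to the kept regions); these 2 were Psmb8 and Psmb9, which were chosen after their values were seen and encode immunoproteasome subunits.

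Markers of other cell types had few members without an untreated peak (7 primitive endoderm, 12 fibroblast and 3 trophoblast markers), and that none was gained in all 4 treated lists does not set them apart from other genes. Of the primitive endoderm, fibroblast and trophoblast markers, 9, 5 and 11 had a peak in all 8 lists. Over both drugs 5 of 9 primitive endoderm regions fell and 0 rose (Col4a1, −0.54 ± 0.08, SE, and −0.19 with kept-region scaling), 2 of 6 fibroblast regions fell and 1 rose, and 9 of 13 trophoblast regions fell and 2 rose. The same numbers passed when adjusted over each list alone. With counts scaled to the kept regions, 4 primitive endoderm regions fell and 3 rose, 2 fibroblast regions fell and 4 rose, and 4 trophoblast regions fell and 2 rose. Ascl2 had −0.20 ± 0.10 (SE, adjusted p = 0.104; 0.14 with counts scaled to the kept regions), and Afp, Acta2 and Col1a1 had no peak. For germline genes 5 of 11 regions fell and 0 rose (4 adjusted over the list alone; 1 fell and 1 rose with counts scaled to the kept regions), with Asz1 and Brdt free of peaks. For imprinted genes 6 of 16 fell and 3 rose, also when adjusted over the list alone, and their median of −0.14 turned to 0.20 with counts scaled to the kept regions (6 rose and 3 fell). Among them were Dlk1 at −0.48 ± 0.08 (SE, adjusted p = 4.54e-04, and 0.108 with counts scaled to the kept regions) and Cdkn1c at −0.29 ± 0.12 (SE, adjusted p = 0.0628; 0.06 with counts scaled to the kept regions). For p53 target genes 5 of 12 fell and 2 rose, also when adjusted over the list alone (5 fell and 4 rose with counts scaled to the kept regions), and Aen and Bax had no peak.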

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

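The count tests in this part, and the test of a background at gene ends, were chosen after the data were seen. The test of the difference between the drugs passed at 2 of 11943 regions, Pfkfb3 among them, where the drugs moved Suz12 counts by different amounts. At Pfkfb3, which encodes a regulator of glycolysis (chromosome 2, 11552228 to 11554828), the log2 change was −1.79 ± 0.16 under DRB and −0.20 ± 0.15 under triptolide (SE). The difference was −1.59 ± 0.22 (SE, edgeR adjusted p = 0.0381). With counts scaled to the kept regions the difference was −1.66 with an adjusted p of 0.0687, so the call rests on the scaling while the size does not. Doses and times differ between the drugs, and no explanation was tested.

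More Suz12 peaks were called after inhibition of transcription, 1.56 times as many. Depth multiplies all regions alike, and it was tested on regions gained in the lists of one drug, read in the counts of the other. These stood at least 1.01 above kept regions in median log2 change, which argues against depth as the whole cause. A higher uniform background adds the same count per kb everywhere. Regions called in untreated lists alone instead lost counts per kb in the other drug's libraries, at −0.413 times the gain of the gained regions, and at gene ends at −0.344 times (bootstrap 95% intervals over regions, −0.455 to −0.381 and −0.433 to −0.301). These counts were scaled to the kept regions, the scaling with the highest median change. The regions called in untreated lists alone were chosen for lacking a peak in the treated lists of 1 drug. The log2 changes of the drugs correlate across regions (Pearson correlation 0.883), so a fall can come with that choice. A background raised alongside the gain is therefore not excluded. The lane stays open too: lane numbers are 1 and 4 for untreated libraries and 3 and 6 for treated ones. Libraries that share index and lane number came from separate runs, so no 1 lane held a whole side, yet lane and treatment cannot be told apart, and a biological cause remains a hypothesis.

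Among the 35 splits of the 8 lists into 4 and 4, 1, the real one, gave as many gained and lost regions (1066, against 74 in the highest other), so another grouping of the lists did not reach that count. For counts, in a fit with 2 groups, 1 of 35 splits called as many regions (6826, against 0 in the highest other by edgeR, where 1698 passed at an unadjusted p under 0.05; DESeq2 was not run on the splits). The real split is also the split by lane number.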

How the results depend on the processing

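Chosen after seeing the data were all alternatives for counts and for the number of gained genes, the within-drug permutation for genes, and leaving out each list for regions of 1 drug, the overlap and the gene lists. The others were set before. Of 497 values under alternatives, 163 that answer a comparison kept their call or direction or, for counts, stayed within 1.5 times; 60 counts moved further and 15 values lost their call; of those for named genes 210 kept their call, 4 lost and 4 gained a call, and 2 reversed; 39 list odds ratios kept their call. Island alternatives were not run. Unless stated, the cause was not tested.

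With permutation within each drug, the ratios of peaks (1.56), covered length (1.44) and genes (1.67) had exact permutation p = 0.0556, the smallest its 36 arrangements allow. For covered length in wider peaks the ratio was 1.35 (exact permutation p = 0.0857). Leaving out 1 list gave 1.48 to 1.72 for peaks, 1.33 to 1.504 for covered length and 1.59 to 1.81 for genes. Without DRB 0 h replicate 1 or 2 or triptolide 0 h replicate 1 or 2, exact permutation p for peaks and genes was 0.0571.

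The replicate block, which pairs libraries by replicate number or index, gave the same ratios of 1.56, 1.44 and 1.67 with exact permutation p = 0.125, the smallest its 16 arrangements allow. Paired libraries share a replicate number for triptolide or an index for DRB, where the names of index TGACCA also share an added digit. No label says that they share a culture. Deviations of paired libraries correlated at 0.375 for DRB and 0.394 for triptolide. In counts the block called 3218 higher and 3429 lower for DRB, 3301 and 3634 for triptolide, 4156 and 4119 for both, and 43 regions differing between the drugs, with fewer residual degrees of freedom.

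Regions gained in all treated lists numbered 518 with wider peaks, 503 at equal list length and 2696 with the rule of 3 of 4 lists; leaving out 1 list gave 1068 to 2131, the highest without triptolide 9 h replicate 1. Lost regions numbered 0, 355 and 55, and 1 to 11 with 1 list left out, the highest without DRB 0 h replicate 1. For DRB, wider peaks gave 1032 gained and 1 lost, equal length 761 and 506, and leaving out 1 list 24 to 136 lost. For triptolide, wider peaks gave 799 and 132, equal length 719 and 664, and leaving out 1 list 1361 to 3283 gained and 73 to 303 lost. Genes gained numbered 462 at equal length and 873 to 1690 with 1 list left out. By construction, shorter lists hold fewer peaks and equal lengths balance gains against losses. With genes gained in DRB lists, 5 gene lists passed in place of 3. Across all alternatives the odds ratio was 3.66 to 11.7 for pluripotency genes, 12.7 to 66.0 for immediate early genes, 0 for olfactory receptors and 112 to 823 for the overlap of the drugs.

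Scaled to the kept regions, counts were higher at 3646 and lower at 601 regions for DRB, 4315 and 595 for triptolide, and 5658 and 1343 for both, with 0 differing between the drugs by edgeR (206 at an unadjusted p under 0.05; DESeq2, with its own scaling, 3). With the sum of all counts 1291, 1324 and 2238 were lower. A mean count of at least 100 left 1621 lower for triptolide, with fewer regions tested. With 1 library left out, the lone sample being assumed to vary like the other groups, DRB had 1089 to 2168 higher and 1203 to 2772 lower, the lowest without the 0 h library of index TGACCA. Triptolide had 1299 to 2947 higher and 1118 to 2999 lower, and 0 to 7 regions differed between the drugs. Cdkn1c, with a log2 fold change of 0.0565, and Ascl2, at 0.14, turned sign over both drugs when scaled to the kept regions.

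Small changes were mostly missed for 1 drug: 6.78% (DRB) and 8.47% (triptolide) of simulated 1.5-fold changes were recovered, against 40.7% over both drugs.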

Other observations

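The gene families and the distance test in this part were chosen after the list results were seen, and the members named were chosen after their values were seen. Families had the same background as the gene lists, so a part played by CpG islands was not tested here either. Among 195 families of at least 10 genes that share a symbol stem, 4 passed after adjustment. Of 266 eligible solute carrier genes 33 gained a Suz12 peak in all treated lists, amino acid transporters Slc38a1, Slc38a2, Slc7a5, Slc1a4 and Slc1a5 among them (odds ratio 2.71, adjusted Fisher's exact p = 2.74e-04). The Klf family of zinc finger factors gained 6 of 15: Klf1, Klf2, Klf3, Klf4, Klf9 and Klf11 (odds ratio 12.5, adjusted Fisher's exact p = 0.00369), of which Klf2 and Klf4 are also on the pluripotency list. The Zbtb family gained 8 of 36, Zbtb7a among them (odds ratio 5.38, adjusted Fisher's exact p = 0.0178). Vomeronasal receptor genes gained 0 of 355 (odds ratio 0, adjusted Fisher's exact p = 2.43e-06).

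Among p53 target genes with changed counts, chosen after their values were seen, Plk2 had the largest change, −1.90 ± 0.13, with peaks in 4 untreated lists and 1 treated list (SE, edgeR adjusted p = 1.06e-06). Phlda3 changed by −1.07 ± 0.11 and Gadd45b by 0.67 ± 0.09 (SE), and each of these 3 had the same sign with counts scaled to the kept regions. Gained genes lay nearer to kept regions than genes with no peak did: 10.2% against 5.04% were within 10 kb of one (odds ratio 2.14, Fisher's exact p = 3.40e-09), with median distances of 115 and 212 kb. The genes with no peak include nearly all of the 1106 olfactory receptor genes, and gene density and CpG islands were not taken into account. Genes are not independent of each other in these tests.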
